A study of Rattus with 9 samples.

How the data were processed

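Poly(A) RNA of rat liver was sequenced in 9 libraries, 3 per group. Per the labels' protocols, messenger RNA was enriched on oligo(dT) beads, fragmented and copied with random primers, the second strand was made with a strand-marking buffer, and the libraries were amplified by PCR. The authors deposited 1 table of FPKM values, fragments scaled to gene length and library total, with 20236 genes and 1 column per library, and replicates were not pooled. The submitters' processing notes name the build Rnor_6.0 and the tools Bowtie2 2.2.3, HISAT2, TopHat2, HTSeq 0.6.0, DESeq2 and DESeq, with no role or order. How the authors computed or filtered the deposited FPKM values, and whether reads were counted by strand, is not given in the sources used here, so genes that overlap on opposite strands may share reads and copies of multi-copy families are uncertain. Poly(A) selection leaves out most RNA without a tail, and the FPKM scale divides each library by its total, so that a few abundant genes can shift all others. All 9 value columns were matched to samples by title, and 0 value columns were left unmapped. Any 2 libraries differed in at least 84.7% of the values, so none was a copy of another.

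The values of a gene were whole multiples of the value of 1 read. With a total per library and a length per gene read from these steps, 100% of the 146433 values above 0 came out as whole reads within a tolerance of 0.001 reads. Lengths were chosen to make the values whole, so that share is no check by itself. The recovered reads, a sum that could have failed to match, came to at least 99.987% of the total that the FPKM scale implies. Depths were 13678658 to 17966670 reads, and 3 reads, the limit that a count of 0 allows, correspond to 0.167 to 0.219 FPKM for a gene of 1 kb. Because the deposited unit is FPKM, a count model was not the main test. Genes of 57 bp, which the scale inflates, were kept in the table.

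Groups came from the group field of the labels and were fixed, with the tests, the gene lists, the rule for named genes and most alternatives, before the data were examined. Replicates were numbered in the order of the samples and pair nothing across groups. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested (11078 genes, 10450 of them protein-coding). Each was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1, which understates the fold change of low genes. All 9 libraries entered 1 fit with the 3 groups as levels and a prior variance that follows the intensity trend. The tests were two-sided, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05 on the adjusted p. The 3 comparisons were model with normal control, pomegranate-high with model, and pomegranate-high with normal control. Separation of the groups was tested with a pseudo-F over all tested genes and all 280 splits of the libraries, an exact permutation test. The steps that share the model libraries were compared with 100 simulations of unchanged groups with the residual spread of each gene.

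For liver biology, 33 gene lists were fixed (sterol, fatty acid, triglyceride, bile acid, lipoprotein, glucose, stress, inflammation, clock and cell type markers), with 555 symbols in all. Of these 521 matched the symbols of the file, 5 matched through the RefSeq gene table of assembly GRCr8, used for names only, and 29 had no match. The 32 lists with at least 3 tested members were tested with limma's camera, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. The repeat with an estimated correlation also rests on the 6 residual degrees of freedom of the fit, in place of nearly the number of genes. A call lost in it therefore cannot be assigned to correlation alone. Beside each list stands the number of members that passed when the adjustment ran over the list alone. Mean log2 changes of lists in the alternatives are means over the members fitted there. Named genes were those past the threshold with a gene symbol other than a clone or locus identifier and no overlap between the groups, the 10 largest changes per direction, or, where fewer than 5 genes passed, the 5 with the smallest p per direction. Up to 4 members per list with the smallest p and 18 lipid and bile acid genes fixed in advance were added to them. Some genes that this rule names are not used here.

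The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, rescaling to TPM, median-of-ratios scaling, and quantile normalization. They also held a fit of the 2 groups compared alone, library quality weights, no intensity trend, an unadjusted p with a fold change of 2, the estimated correlation, and leaving out each library in turn. Chosen after the data were seen were limma's voom on recovered reads, the mitochondrial read share as a covariate, a fit excluding the 3 libraries with the highest mitochondrial share, nuclear protein-coding genes only and camera on 798 gene ontology terms of 10 to 200 members. The fit excluding 3 libraries leaves 1 pomegranate-high library, which is assumed to vary like the other groups.

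The limma step was tested on simulated data for model with normal control, with 11078 genes and 20 runs. It recovered 30.7% of genes changed by 1 log2 unit, 83.2% at 2, 94.8% at 3 and 98.9% at 4, with 4.93% of calls false and a slope of fitted on true change of 1.01. Camera found the shifted list in 100% of the runs and called on average 0 of the 30 unshifted lists. The simulated genes varied independently of each other. These runs therefore cannot show how often lists of correlated genes are called falsely at the preset correlation. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.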

Results

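Gene expression was measured by RNA sequencing in 9 liver libraries of Sprague-Dawley rats, an outbred laboratory strain, 3 each from a normal control, a model and a pomegranate-high group, after 8 weeks of administration. The series concerns hyperlipidemia, a raised level of lipids in the blood, and pomegranate as its treatment. The labels describe neither how the model was made nor the pomegranate preparation and its dose. They do not give the sex of the animals, and they do not say that each library came from a separate animal, so p-values of single genes measure the spread between these libraries. The list tests at the preset correlation set genes of a list against other genes. Their p-values rest on the spread over genes and do not measure that between libraries. Groups were taken from the group field. The titles of the libraries in the model group begin with SG and those in the pomegranate-high group with M, letters that the labels do not explain, so every direction that involves these arms rests on the group field alone. The deposited FPKM values gave back depths of 16166083, 16617769 and 17966670 reads for the controls and 13678658, 16364483 and 17064905 for the model arm. For the pomegranate-high arm they were 16363407, 14077241 and 16280762 reads. At these depths 3 reads on a gene of 1 kb correspond to 0.167 to 0.219 FPKM, a floor that covers counting error only. FPKM values are given as mean ± SD of 3 libraries, and log2 differences, on the scale of log2(FPKM + 1), with their standard error (SE).

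The share of reads on mitochondrially encoded genes was 6.38%, 4.18% and 4.17% in the controls, 14.5%, 6.40% and 4.99% in the model arm, and 9.62%, 11.4% and 4.22% in the pomegranate-high arm. The 3 libraries with the highest shares, model replicate 1 and pomegranate-high replicates 1 and 2, also had the lowest median correlation with the other 8 libraries (0.929, 0.931 and 0.922, against 0.963 to 0.970 for the rest). Albumin, the main secreted hepatocyte protein, took 4.93% and 4.85% of the reads in pomegranate-high replicates 1 and 2 and 6.65% or more in the other libraries. The median SD of a gene's log2 value was 0.23 within the controls, 0.33 within the model arm and 0.34 within the pomegranate-high arm. Over all genes tested, libraries of one group were not closer to each other than the spread between libraries allows (pseudo-F 1.34, one-sided exact permutation p = 0.143 over 280 splits, smallest possible 0.00357). Without pomegranate-high replicate 3 the exact permutation p was 0.025.

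**Figure D1:**
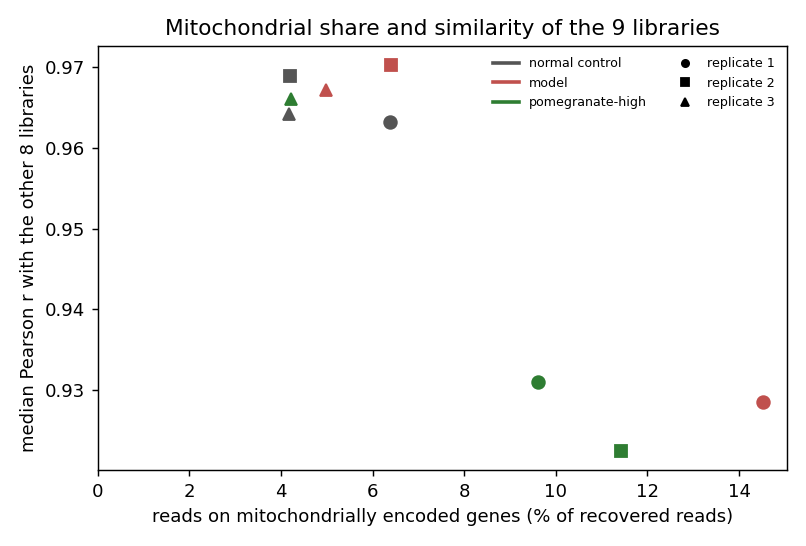
Each point is 1 of the 9 liver libraries, placed by the percent of its recovered reads on mitochondrially encoded genes (x axis) and by its median Pearson correlation of log2(FPKM + 1) with the other 8 libraries (y axis); colour gives the group and shape the replicate. Model replicate 1 (14.5%) and pomegranate-high replicates 1 and 2 (9.62% and 11.4%) lie apart at correlations of 0.922 to 0.931.

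The first comparison asked how livers of the arm labelled model differed from normal control livers. Endothelial, red blood cell, macrophage and cholesterol synthesis genes fell as lists in the model arm at the preset correlation between genes, and none of the 11 lists called in this comparison passed with an estimated correlation (smallest adjusted p = 0.108). All 11 measured members of the list of liver endothelial markers were lower (median log2 difference −0.80, camera adjusted p = 6.58e-14, and adjusted p = 0.108 with an estimated correlation), and 6 of them passed when adjusted over the list alone. Stab2, a scavenger receptor of the sinusoidal endothelium, stood at 3.84 ± 0.150 FPKM in controls and 1.56 ± 0.340 in the model arm (log2 difference −0.93 ± 0.20 SE). Kdr, a receptor for vascular endothelial growth factor, stood at 9.74 ± 0.791 and 4.45 ± 0.885 FPKM (−0.99 ± 0.24), and the hyaluronan receptor Lyve1 at 13.7 ± 4.13 and 6.05 ± 1.44 FPKM (−1.05 ± 0.30). All 5 red blood cell markers were lower (median −0.83, adjusted p = 9.75e-07, and adjusted p = 0.108 with an estimated correlation), and 2 passed when adjusted over the list alone. They were the globin genes Hbb (215 ± 42.8 and 84.2 ± 56.9 FPKM) and Hba-a3, whose reads can be shared with other globin copies. Of the Kupffer cell and macrophage markers, 12 of 13 were lower (median −0.79, adjusted p = 1.05e-06, and adjusted p = 0.570 with an estimated correlation), with 0 passing when adjusted over the list alone. Among them the scavenger receptor gene Marco stood at 36.2 ± 15.5 and 11.2 ± 7.24 FPKM (−1.71 ± 0.56). The mean change of this list was −0.76 with all libraries and −0.37 without model replicate 1, the library with the highest mitochondrial share, where the adjusted p was 0.000133. The stellate cell and matrix markers, which mark another cell type of the liver, had a median log2 difference of −0.04 (5 of 13 higher, adjusted p = 0.960).

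Cholesterol synthesis genes were lower for 18 of 20 members (median log2 difference −0.60, camera adjusted p = 9.75e-07, and adjusted p = 0.570 with an estimated correlation), 1 of which passed when adjusted over the list alone. That gene was Tm7sf2, which encodes a sterol reductase (25.6 ± 11.6 FPKM in controls, 5.25 ± 1.41 in the model arm, −2.03 ± 0.33 SE, adjusted p = 0.304 over all genes). Cyp51, a demethylase of lanosterol, stood at 25.1 ± 19.0 and 10.5 ± 1.64 FPKM, a log2 difference of −0.95 that was −0.39 without control replicate 2. The 3 controls lay at −0.32, 0.64 and −0.32 around their mean for the cholesterol synthesis list and the model libraries at −0.67, −0.44 and −0.55. Without control replicate 2 the mean change was −0.24 in place of −0.55 and the adjusted p 0.0316. Members of the list of fatty acid oxidation and PPAR-alpha targets were lower for 25 of 27 genes (median −0.38, adjusted p = 3.92e-05, and adjusted p = 0.667 with an estimated correlation), with 0 passing when adjusted over the list alone. Among them Cyp4a2, a fatty acid hydroxylase of a multi-copy family, stood at 891 ± 165 and 442 ± 94.2 FPKM. Without model replicate 1 the mean change of this list was −0.16 in place of −0.40 (adjusted p = 0.00473), and with the mitochondrial share as a covariate its call ended (0.0873, mean change −0.07). Triglyceride storage and lipid droplets (14 of 18 lower, median −0.33, adjusted p = 0.0186) and interferon response (16 of 20 lower, median −0.38, adjusted p = 0.0227) also fell as lists. Each had adjusted p = 0.667 with an estimated correlation, with 0 passing when adjusted over the list alone. The triglyceride list lost its call without control replicate 2 (0.0743, mean change −0.24 in place of −0.30) or model replicate 1 (0.139, −0.11), with a mean FPKM of at least 5 (0.110, −0.25) and with the mitochondrial share as a covariate (0.546, 0.01). The interferon list lost it without control replicate 1 (0.20, mean change −0.27 in place of −0.31), model replicate 1 (0.249, −0.06) or model replicate 2 (0.211, −0.31), and its change was −0.56 without model replicate 3. With library quality weights the interferon response call also ended (0.966, mean change 0.04).

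Mitochondrially encoded transcripts, male-higher genes, circadian clock genes and immediate early genes rose as lists in the model arm. All 12 mitochondrially encoded transcripts were higher (median log2 difference 0.66, camera adjusted p = 0.000171, and adjusted p = 0.667 with an estimated correlation), at levels of 1.59, 0.32 and 0.00 in the 3 model libraries relative to the control mean. Without model replicate 1 their mean change was 0.16 in place of 0.64 and the adjusted p 0.656, and without control replicate 3 it was 0.42 (0.0376). The call of the mitochondrially encoded transcripts also ended with library quality weights (0.101, 0.28) and with the mitochondrial share, which these transcripts make up, as a covariate (0.476, −0.06). All 6 members of the list sex-biased rat liver genes, male-higher were higher (median 0.59, adjusted p = 0.000272, and adjusted p = 0.240 with an estimated correlation). Cyp2c11, a male-specific steroid hydroxylase of a multi-copy family, stood at 414 ± 64.3 and 702 ± 217 FPKM. Without control replicate 3 the mean change of this list was 0.33 in place of 0.53 (adjusted p = 0.0114). Of the members of the circadian clock list, 11 of 15 were higher (median 0.17, adjusted p = 0.0259, and adjusted p = 0.240 with an estimated correlation), and when adjusted over the list alone 3 were higher and 1 lower. The transcription factor gene Dbp, a clock output, stood at 12.2 ± 2.42 FPKM in controls and 62.8 ± 36.2 in the model arm (2.05 ± 0.49 SE). Per3 stood at 2.29 ± 0.718 and 4.59 ± 0.761 FPKM and Nr1d2 at 5.23 ± 1.86 and 10.3 ± 0.949 FPKM. Arntl, the core activator of the clock, stood at 7.34 ± 1.37 and 2.60 ± 0.832 FPKM (−1.23 ± 0.32). The list joins genes of opposite phase. Its 4 early-phase genes changed by −0.68 and its 8 late-phase genes by 0.80 on average, so its direction does not hold for all its members. The circadian clock call was lost without control replicate 1 (0.0653), though its mean change stayed at 0.27, and without model replicate 3 (0.167, 0.17). It was also lost with a mean FPKM of at least 5 (0.0818, 0.25) and in a fit of the 2 groups alone (0.0608, 0.27). Immediate early genes were higher for 10 of 16 members (median 0.41, adjusted p = 0.0273, and adjusted p = 0.667 with an estimated correlation). Their 3 model libraries lay at −0.91, 0.38 and 1.62, and the call was lost without control replicate 2 (adjusted p = 0.609, mean change 0.01) and turned to the lower side, not passing, without model replicate 3 (0.538, mean change −0.26). With all libraries the mean change of the immediate early list was 0.36, and it was 0.66 without control replicate 3 and 1.0 without model replicate 1. The immediate early call was also lost with no filter on low values (0.0612) and in a fit of the 2 groups alone (0.0608), both with the mean change unmoved. In the mitochondrial, male-higher and immediate early lists 0 members passed when adjusted over the list alone. A fit chosen after the data were seen excluded the 3 libraries with the highest mitochondrial share. In it the call ended for interferon response (mean change −0.06 in place of −0.31). That of the mitochondrially encoded transcripts ended as well (0.16 in place of 0.64), but their own share set the exclusion. The circadian clock call ended too (0.0858), though its mean change grew from 0.27 to 0.36.

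**Figure D2:**
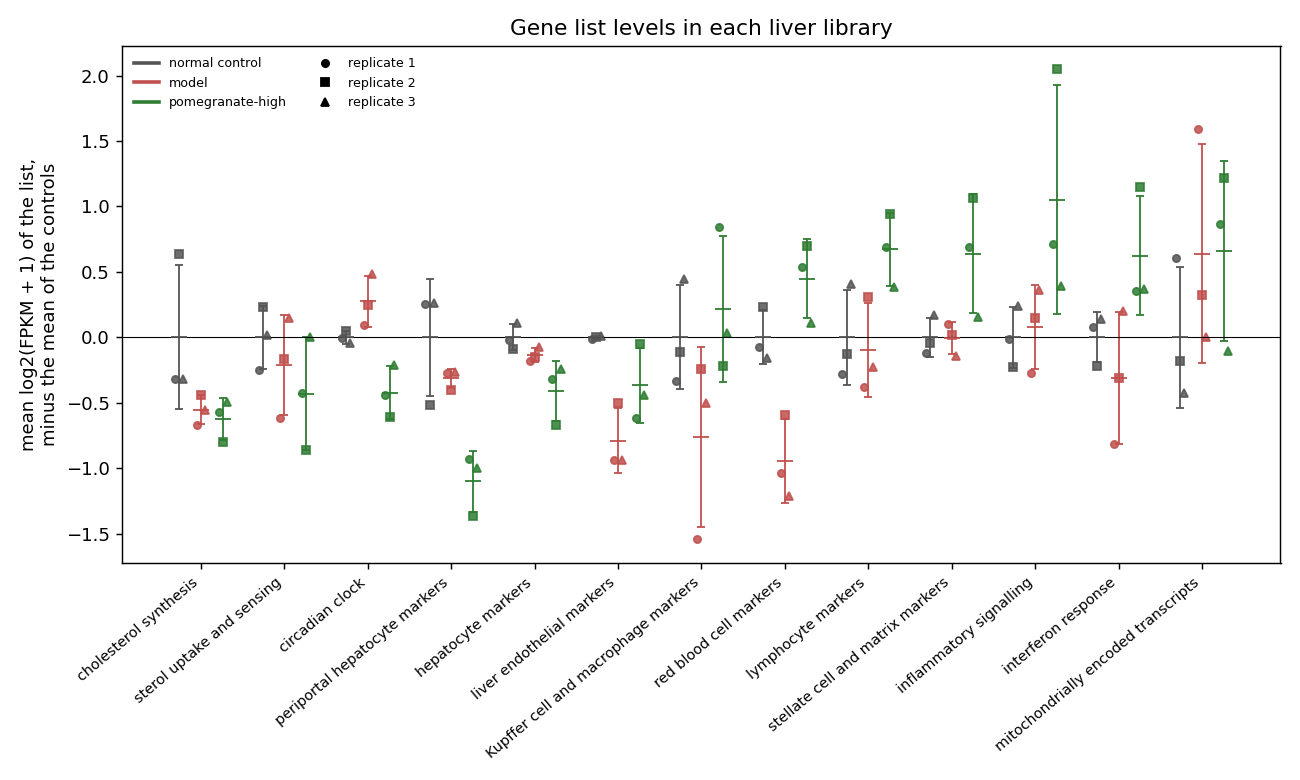
Mean log2(FPKM + 1) over the members of 13 gene lists in each library, minus the mean of the 3 normal controls (y axis, log2 units), with the lists along the x axis; colour gives the group, shape the replicate, and horizontal and vertical lines the mean and SD of 3 libraries. The 3 model libraries lie at −0.93, −0.50 and −0.94 for endothelial markers, and the 3 pomegranate-high libraries at 0.71, 2.05 and 0.39 for inflammatory signalling.

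By limma with Benjamini-Hochberg adjustment, 1 of 11078 genes differed between the model arm and the controls, and 0 were higher. That gene was RT1-CE16 (ENSRNOG00000059770, chromosome 20, 3791629 to 3796275, minus strand, build Rnor_6.0), a class I gene of the major histocompatibility complex whose reads can be shared with related copies. It stood at 3.99, 6.33 and 8.29 FPKM in the controls and was listed at 0 in all 3 model libraries (adjusted p = 0.0332, range over 21 alternatives 0.00130 to 0.381). Of the 9 fits that each left out 1 library, RT1-CE16 passed only without control replicate 1 (adjusted p = 0.0424) and without pomegranate-high replicate 1 (0.0123). At an unadjusted p under 0.05, regrouping the 6 libraries of both groups otherwise than labelled gave 100 to 771 genes. The labelled groups gave 330, 133 higher and 197 lower, where chance alone would give 553.9 on average. Leaving out 1 library moved this count between 189 (without control replicate 3) and 444 (without model replicate 2). This balance turned without model replicate 1 (166 higher, 112 lower), with the mitochondrial share as a covariate (254 and 169) and in the fit excluding the 3 libraries with the highest share (317 and 237). Voom on recovered reads called 0 genes and gave 342 at that level. In 8.79% of the genes the 3 libraries of one group all lay above those of the other, a share that chance puts at 10% on average. Among genes that did not pass, those with the smallest p included Amdhd1, an enzyme of histidine breakdown (72.5 ± 17.7 FPKM in controls, 14.8 ± 3.23 in the model arm, −2.20 ± 0.31, adjusted p = 0.172). Tor3a stood at 7.23 ± 2.52 and 1.09 ± 0.425 FPKM (−1.96 ± 0.32). Hba-a3 stood at 17.0 ± 0.284 and 5.60 ± 0.574 FPKM (−1.45 ± 0.25). On the higher side they included Mup4, a major urinary protein gene of a multi-copy family (2.66 ± 0.49, adjusted p = 0.412), and Hsd17b2, a steroid dehydrogenase (61.9 ± 14.4 and 209 ± 94.2 FPKM, 1.66 ± 0.43). Slc16a4 stood at 8.27 ± 2.83 and 18.8 ± 3.79 FPKM (1.12 ± 0.29) and Adam8 at 0.955 ± 0.297 and 2.35 ± 0.373 FPKM (0.78 ± 0.21).

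None of 18 lipid and bile acid genes named before the data were examined passed in any of the 3 comparisons by limma, nor by voom on recovered reads. At an unadjusted p under 0.05 there were 2 of them in the first comparison. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 15.8 ± 1.98 FPKM in controls and 83.1 ± 80.2 in the model arm (1.90 ± 0.58 SE). The model libraries had 175, 28.9 and 45.1 FPKM of Cyp7a1, and without model replicate 1 its log2 difference was 1.16. Srebf1, a regulator of fatty acid synthesis, stood at 31.3 ± 15.9 and 84.9 ± 43.2 FPKM (1.39 ± 0.44). Fasn stood at 4.72 ± 4.00 and 4.30 ± 1.97 FPKM, and Cpt1a at means of 116 and 112.

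**Figure D3:**
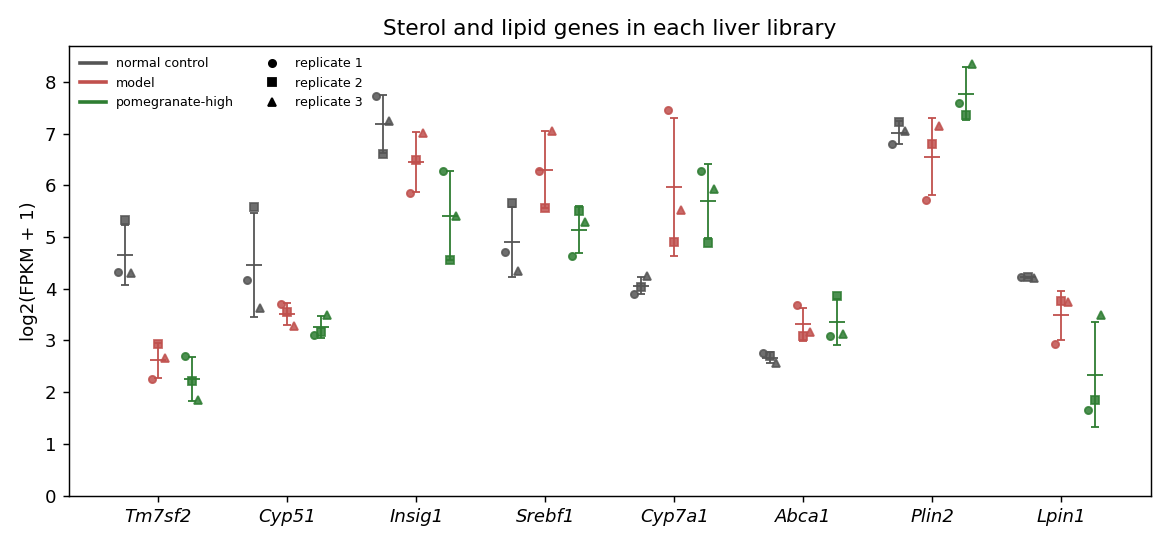
Expression of 8 sterol and lipid genes in each library as log2(FPKM + 1) (y axis), with the genes along the x axis; colour gives the group, shape the replicate, and lines the mean and SD of 3 libraries. None passed over all genes in any comparison; Tm7sf2 lies lower in all 6 libraries of the model and pomegranate-high arms (means of 5.25 and 3.92 FPKM) than in the 3 controls (25.6 FPKM).

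The second comparison asked how livers of the arm labelled pomegranate-high differed from those of the arm labelled model. Clock genes and periportal hepatocyte genes fell as lists, and interferon, inflammatory, immune cell, matrix and globin genes rose as lists, at the preset correlation between genes. Of the 16 lists called, only the circadian clock list passed with an estimated correlation as well. Of the 15 circadian clock genes 11 were lower (median log2 difference −0.78, camera adjusted p = 3.38e-07, and adjusted p = 0.0313 with an estimated correlation, the only list in the 3 comparisons that held with it). The estimate for this list was −0.00041, below the preset 0.01. In the other lists called here it ran from 0.058 (glucose metabolism and insulin signalling) to 0.65 (lymphocyte markers), so the allowance for correlation was milder for the clock list. The unadjusted camera p of the clock list still rose from 2.11e-08 to 0.000977, because the repeat also rests on only 6 residual degrees of freedom. When adjusted over the list alone 9 were lower and 2 higher. Nr1d1, a repressor in the clock loop, stood at 28.8 ± 28.6 FPKM in the model arm and 2.34 ± 0.216 in the pomegranate-high arm (−2.58 ± 0.71 SE). Dbp stood at 62.8 ± 36.2 and 14.6 ± 6.12 FPKM (−1.86 ± 0.49) and Per3 at 4.59 ± 0.761 and 1.02 ± 0.201 FPKM (−1.47 ± 0.22, adjusted p = 0.158 over all genes). Arntl stood at 2.60 ± 0.832 and 8.44 ± 3.86 FPKM (1.34 ± 0.32). Early-phase genes of the list changed by 0.78 and late-phase genes by −1.30 on average, so its fall does not hold for all its members. Beside the estimated correlation, the circadian clock call held in the 22 alternatives that kept the preset correlation, the 9 that left out 1 library included (highest adjusted p = 0.000203).

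**Figure D4:**
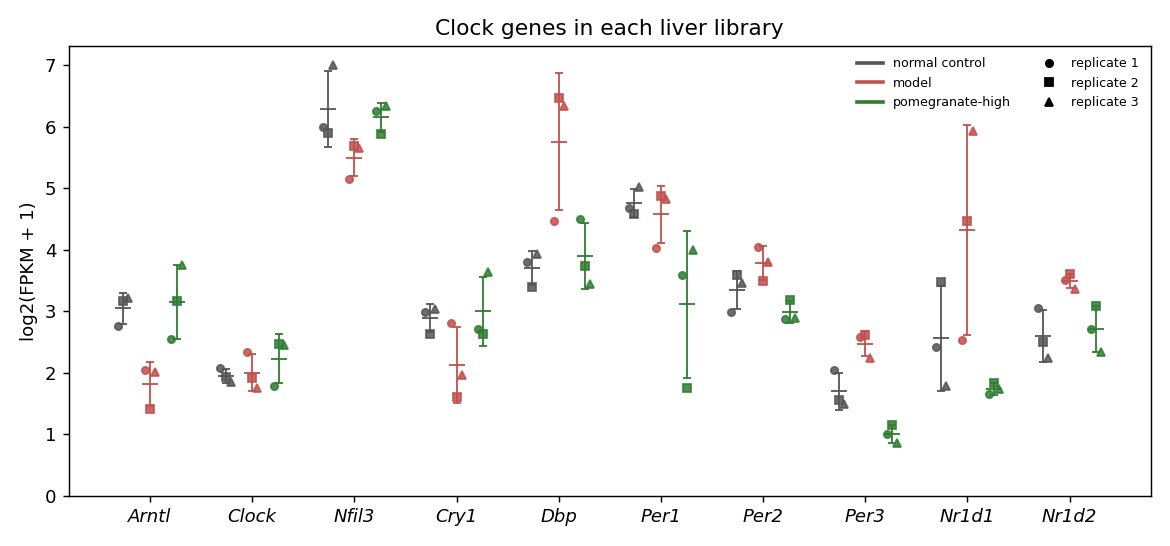
Expression of 10 circadian clock genes in each library as log2(FPKM + 1) (y axis), with the genes along the x axis; colour gives the group, shape the replicate, and lines the mean and SD of 3 libraries. Per3 lies lower in all 3 pomegranate-high libraries (mean 1.02 FPKM) than in the 3 model libraries (4.59 FPKM), and Arntl higher (8.44 and 2.60 FPKM).

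Interferon response genes were higher for 18 of 20 members in the pomegranate-high arm (median log2 difference 1.04, camera adjusted p = 2.89e-07, and adjusted p = 0.349 with an estimated correlation), and 10 passed when adjusted over the list alone. Isg15, a ubiquitin-like protein induced by interferon, stood at 5.21 ± 2.82 FPKM in the model arm and 17.7 ± 10.4 in the pomegranate-high arm (1.57 ± 0.44 SE). The antiviral gene Mx1 stood at 1.76 ± 1.04 and 5.28 ± 1.80 FPKM (1.22 ± 0.32). All 13 Kupffer cell and macrophage markers were higher (median 0.99, adjusted p = 4.43e-05, and adjusted p = 0.382 with an estimated correlation). Among them Cd68 (17.7 ± 7.18 and 57.4 ± 30.7 FPKM) and the lysozyme gene Lyz2 (28.2 ± 11.2 and 108 ± 65.9 FPKM) were the 2 that passed when adjusted over the list alone. Without model replicate 1 the mean change of the macrophage list was 0.59 in place of 0.98 (adjusted p = 0.00371). All 8 lymphocyte markers were higher (median 0.74, adjusted p = 4.43e-05, and adjusted p = 0.349 with an estimated correlation), 5 of them passing when adjusted over the list alone. The T cell gene Cd8a stood at 2.03 ± 0.784 and 7.04 ± 3.60 FPKM. Inflammatory signalling genes were higher for 15 of 16 members (median 0.68, adjusted p = 6.03e-05, and adjusted p = 0.382 with an estimated correlation), and Cxcl10 and Tlr2 passed when adjusted over the list alone. Cxcl10, a chemokine induced by interferon, stood at 7.93 ± 5.54 and 67.2 ± 75.5 FPKM. The chemokine gene Cxcl1 stood at 6.48 ± 4.77 and 206 ± 309 FPKM, and without pomegranate-high replicate 2 the mean change of the inflammatory list was 0.48 in place of 0.97 (adjusted p = 0.0224). Stellate cell and matrix markers were higher for 12 of 13 members (median 0.62, adjusted p = 0.000393, and adjusted p = 0.327 with an estimated correlation). The collagen genes Col3a1 (16.1 ± 2.92 and 46.9 ± 17.2 FPKM) and Col1a1 (1.05 ± 0.463 and 5.40 ± 4.57 FPKM) passed when adjusted over the list alone. Beside these groups, the pomegranate-high libraries with the 2 highest mitochondrial shares of the arm, replicates 1 and 2, lay at 0.71 and 2.05 for inflammatory signalling and replicate 3 at 0.39, all relative to the control mean. For interferon response the values were 0.36, 1.15 and 0.37, for lymphocyte markers 0.69, 0.94 and 0.39, and for stellate markers 0.69, 1.06 and 0.16. The Kupffer cell and macrophage markers had another order, at 0.84, −0.22 and 0.03. Without pomegranate-high replicate 2 the log2 difference was 1.68 in place of 2.56 for Cxcl10, 2.04 in place of 3.53 for Cxcl1 and 0.90 in place of 1.45 for Col1a1. In a fit excluding the 3 libraries with the highest mitochondrial share, chosen after the data were seen, the calls ended for the Kupffer cell and macrophage markers (0.0552, mean change 0.40 in place of 0.98), lymphocyte markers (0.175, 0.35 in place of 0.77), inflammatory signalling (0.775, 0.14 in place of 0.97) and stellate cell and matrix markers (0.338, 0.22 in place of 0.64), while interferon response still passed (0.0102) with a mean change of 0.43 in place of 0.93. That fit leaves 1 pomegranate-high library, which is assumed to vary like the other groups.

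All 5 red blood cell markers were higher in the pomegranate-high arm than in the model arm (median log2 difference 1.42, camera adjusted p = 9.05e-07, and adjusted p = 0.0761 with an estimated correlation), and 4 passed when adjusted over the list alone. Hbb stood at 84.2 ± 56.9 and 282 ± 85.1 FPKM (1.88 ± 0.43 SE), and Alas2, the heme synthesis enzyme of red cells, at 0.941 ± 0.325 and 3.22 ± 1.48 FPKM (1.07 ± 0.29). Liver endothelial markers were higher for 10 of 11 members (median 0.36, adjusted p = 0.00762, and adjusted p = 0.382 with an estimated correlation). This endothelial call was lost without model replicate 3 (0.0587, mean change 0.35 in place of 0.42), without pomegranate-high replicate 2 (0.0750, 0.26) and in the fit excluding the 3 libraries with the highest mitochondrial share (0.0949, 0.28). All 3 pancreas and adipose markers were higher (median 1.17, adjusted p = 0.0388, and adjusted p = 0.349 with an estimated correlation). The pancreas and adipose call was lost without model replicate 1 (0.0594, mean change 1.04 in place of 1.14), model replicate 2 (0.0713, 1.27), pomegranate-high replicate 1 (0.166, 0.86) or pomegranate-high replicate 2 (0.0560, 0.96). It also ended with library quality weights (0.0527, 1.24), with no filter on low values (0.240, 0.43) and in the fit excluding the 3 libraries (0.994, 0.12). Among them Fabp4, a fatty acid carrier of fat and endothelial cells, stood at 2.62 ± 1.86 and 15.8 ± 14.5 FPKM, a log2 difference of 1.81 that was 1.08 without pomegranate-high replicate 2 and 2.72 without pomegranate-high replicate 3. For the endothelial and the pancreas and adipose lists 0 members passed when adjusted over the list alone.

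All 10 periportal hepatocyte markers were lower in the pomegranate-high arm than in the model arm (median log2 difference −0.62, camera adjusted p = 8.61e-07, and adjusted p = 0.165 with an estimated correlation), with 0 passing when adjusted over the list alone. Sds, serine dehydratase, stood at 257 ± 134 FPKM in the model arm and 39.5 ± 28.2 in the pomegranate-high arm (−2.78 ± 0.95 SE). Hal, histidine ammonia-lyase, stood at 88.5 ± 29.6 and 46.4 ± 19.2 FPKM (−0.94 ± 0.33), and Arg1, the urea cycle arginase, at 788 ± 13.7 and 529 ± 112 FPKM (−0.59 ± 0.26). Of the hepatocyte markers 9 of 14 were lower (median −0.22, adjusted p = 0.00434, and adjusted p = 0.327 with an estimated correlation), 0 of them passing when adjusted over the list alone. Without pomegranate-high replicate 2 the adjusted p of the hepatocyte markers was 0.0671 and the mean change −0.15 in place of −0.27. Tat, tyrosine aminotransferase, stood at 1122 ± 164 and 558 ± 314 FPKM, a log2 difference of −1.22 that was −0.61 without pomegranate-high replicate 2. Fatty acid synthesis genes were lower for 12 of 15 members (median −0.44, adjusted p = 0.00278, and adjusted p = 0.382 with an estimated correlation), and the 1 that passed when adjusted over the list alone was higher. That gene was Scd2, a desaturase (1.98 ± 0.604 and 7.27 ± 3.24 FPKM). Srebf1 stood at 84.9 ± 43.2 and 35.5 ± 10.5 FPKM (−1.15 ± 0.44). The fatty acid synthesis call ended in the fit excluding the 3 libraries with the highest mitochondrial share (0.155, mean change −0.20 in place of −0.34). Genes of glucose metabolism and insulin signalling were lower for 13 of 17 members (median −0.39, adjusted p = 0.00548, and adjusted p = 0.327 with an estimated correlation), 0 of them passing when adjusted over the list alone. That call was lost without model replicate 3 (0.0675, mean change −0.05 in place of −0.23) or pomegranate-high replicate 2 (0.0839, mean change −0.08). The mean change of the glucose list was −0.42 without model replicate 1 and −0.39 without pomegranate-high replicate 3. In the fit excluding the 3 libraries with the highest mitochondrial share the mean change was −0.09 for glucose metabolism and insulin signalling (adjusted p = 0.0453) and −0.13 for hepatocyte markers (0.0431).

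Sterol uptake and sensing (10 of 14 lower, median log2 difference −0.20, camera adjusted p = 0.0480), bile acid synthesis (8 of 12 lower, median −0.21, 0.0480) and bile acid and sterol transport and their receptors (11 of 16 lower, median −0.13, 0.0470) fell as lists close to the threshold. With an estimated correlation the adjusted p = 0.597, 0.382 and 0.382, and 0 members passed when adjusted over the list alone. Under median-of-ratios scaling, which moved the median of all genes from 0.09 to −0.01, none of these 3 lists passed, though their mean changes grew (−0.32, −0.32 and −0.23, from −0.22, −0.20 and −0.13). All 3 calls were also lost with rescaling to TPM, quantile normalization and voom on recovered reads, again with larger mean changes. The first 2 were lost with a pseudocount of 0.1 (both 0.0513), the last 2 with library quality weights (0.0914 and 0.0839), bile acid synthesis with the mitochondrial share as a covariate (0.0508, mean change −0.20) and the transport list with no filter on low values (0.0801, −0.10). The sterol uptake and sensing call was lost without control replicate 3 (0.0580; the controls do not enter its mean change), model replicate 2 (0.0575, mean change −0.19), model replicate 3 (0.315) or pomegranate-high replicate 2 (0.617). Its mean change of −0.22 was −0.04 without model replicate 3 and −0.00013 without pomegranate-high replicate 2, and −0.42 and −0.43 without model replicate 1 and pomegranate-high replicate 3. The bile acid synthesis call was lost without control replicate 2 (0.0511), model replicate 1 (0.456, mean change −0.08 in place of −0.20) or pomegranate-high replicate 2 (0.422, −0.06), and its change was −0.37 without pomegranate-high replicate 3. The call of bile acid and sterol transport and their receptors was lost without model replicate 1 (0.213, mean change −0.13, as with all libraries), model replicate 3 (0.0723, −0.09), pomegranate-high replicate 2 (0.215, −0.06) or pomegranate-high replicate 3 (0.0770, −0.23). In the fit excluding the 3 libraries with the highest mitochondrial share these 3 calls ended, at mean changes of 0.01 (0.714), 0.25 (0.358) and 0.07 (0.714) in the order given above. Cyp7a1 stood at 83.1 ± 80.2 FPKM in the model arm and 55.0 ± 24.2 in the pomegranate-high arm. Its log2 difference of −0.27 turned to 0.48 without model replicate 1 and to 0.72 in the fit excluding the 3 libraries with the highest mitochondrial share. Cholesterol synthesis genes were lower for 12 of 20 members and did not pass as a list (median −0.12, adjusted p = 0.109).

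By limma with Benjamini-Hochberg adjustment, 1 of 11078 genes differed between the pomegranate-high and the model arm, and 0 were lower. Hba-a3 (chromosome 10, 15577249 to 15577977, minus strand), a globin gene with near-identical copies, stood at 4.94, 5.84 and 6.01 FPKM in the model arm and 29.6, 41.7 and 21.5 in the pomegranate-high arm. The controls had 17.3, 17.0 and 16.7 FPKM of Hba-a3 (pomegranate-high against model log2 difference 2.23 ± 0.25 SE, adjusted p = 0.0386, range over 22 alternatives 0.00715 to 0.453). Of the 9 fits that each left out 1 library, Hba-a3 passed only without pomegranate-high replicate 3 (adjusted p = 0.0131). At an unadjusted p under 0.05, regrouping the 6 libraries of both arms otherwise than labelled gave 154 to 2216 genes. The labelled arms gave 963, where chance alone would give 553.9 on average. Leaving out 1 library moved this count between 597 (without pomegranate-high replicate 2) and 1984 (without pomegranate-high replicate 3), with 640 without model replicate 3. They were 789 higher and 174 lower, and under median-of-ratios scaling 572 higher and 387 lower. Voom on recovered reads called 0 genes and gave 924 at that level. Without pomegranate-high replicate 3, the library of the arm with the lowest mitochondrial share, 77 genes passed, 49 higher and 28 lower. Among the other genes with the smallest p were Tor3a (1.09 ± 0.425 and 8.40 ± 3.68 FPKM, 2.13 ± 0.32, adjusted p = 0.158) and Asns, asparagine synthetase (1.84 ± 0.316 and 6.99 ± 0.951 FPKM, 1.49 ± 0.23, adjusted p = 0.158). Apobec1, the cytidine deaminase that edits apolipoprotein B transcripts, stood at 2.01 ± 0.189 and 6.07 ± 2.27 FPKM (1.19 ± 0.23), and Tcf21 at 3.02 ± 0.932 and 8.02 ± 1.58 FPKM (1.18 ± 0.23). On the lower side Galr3 stood at 1.85 ± 0.707 and 0.149 ± 0.0399 FPKM (−1.28 ± 0.23). Arhgef26 stood at 11.3 ± 2.15 and 4.42 ± 0.825 FPKM (−1.17 ± 0.26), and Mup4, of a multi-copy family, differed by −2.56 ± 0.49. In 10.8% of the genes the groups did not overlap, where chance gives 10% on average.

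The third comparison set livers of the arm labelled pomegranate-high against normal control livers. Periportal hepatocyte, hepatocyte, cholesterol synthesis and clock genes fell as lists, while inflammatory, interferon, matrix and lymphocyte genes rose as lists, at the preset correlation between genes. None of the 13 lists called in this comparison passed with an estimated correlation (smallest adjusted p = 0.176). Of the periportal hepatocyte markers 9 of 10 were lower (median log2 difference −0.89, camera adjusted p = 1.93e-07, and adjusted p = 0.176 with an estimated correlation), and 5 passed when adjusted over the list alone. Hal stood at 176 ± 28.2 FPKM in controls and 46.4 ± 19.2 in the pomegranate-high arm (−1.96 ± 0.33 SE). Gls2, a glutaminase, stood at 185 ± 64.0 and 68.9 ± 17.8 FPKM (−1.38 ± 0.32), and Pck1, a key enzyme of gluconeogenesis, at 2683 ± 666 and 1125 ± 552 FPKM (−1.37 ± 0.41). Of the hepatocyte markers 13 of 14 were lower (median −0.30, adjusted p = 0.00130, and adjusted p = 0.302 with an estimated correlation), with 0 passing when adjusted over the list alone. Cholesterol synthesis genes were lower for 18 of 20 members (median −0.60, adjusted p = 2.82e-07, and adjusted p = 0.465 with an estimated correlation), and 1 passed when adjusted over the list alone. It was Tm7sf2 (25.6 ± 11.6 and 3.92 ± 1.45 FPKM, −2.39 ± 0.33, adjusted p = 0.0861 over all genes). Without control replicate 2 the mean change of the cholesterol synthesis list was −0.31 in place of −0.62 (adjusted p = 0.00231). Sterol uptake and sensing genes were lower for 9 of 14 members (median −0.35, adjusted p = 0.00337, and adjusted p = 0.492 with an estimated correlation). Insig1, a sterol sensor (152 ± 57.5 and 46.7 ± 27.2 FPKM), and Stard4, a sterol carrier (5.67 ± 1.11 and 2.69 ± 0.734 FPKM), passed when adjusted over the list alone. The sterol uptake and sensing call was lost without pomegranate-high replicate 2 (0.0889, mean change −0.21 in place of −0.43, against −0.65 without pomegranate-high replicate 3), with the mitochondrial share as a covariate (0.297, −0.08) and in the fit excluding the 3 libraries with the highest mitochondrial share (0.447, near 0). With the covariate 4 other calls ended, for stellate cell and matrix markers, triglyceride storage and lipid droplets, glucose metabolism and insulin signalling and mitochondrially encoded transcripts, all given below. Circadian clock genes were lower for 10 of 15 members (median −0.36, adjusted p = 0.00164, and adjusted p = 0.176 with an estimated correlation), and Per1, Per3 and Usp2 passed when adjusted over the list alone. Per1 stood at 26.4 ± 4.54 and 9.48 ± 6.47 FPKM and Usp2 at 14.8 ± 4.03 and 5.72 ± 3.56 FPKM. Early-phase clock genes changed by 0.09 and late-phase ones by −0.50 on average. Without pomegranate-high replicate 2 the log2 difference was −0.97 in place of −1.65 for Per1, −0.84 in place of −1.38 for Usp2 and −0.90 in place of −1.37 for Pck1. In the fit excluding the 3 libraries with the highest mitochondrial share the mean change was −0.24 in place of −0.41 for hepatocyte markers (adjusted p = 0.00257) and −0.21 in place of −0.42 for circadian clock (0.00408).

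Inflammatory signalling genes were higher for 14 of 16 members in the pomegranate-high arm than in controls (median log2 difference 0.75, camera adjusted p = 0.000454, and adjusted p = 0.492 with an estimated correlation), and 5 passed when adjusted over the list alone. Cxcl10 stood at 3.08 ± 2.40 FPKM in controls and 67.2 ± 75.5 in the pomegranate-high arm (3.63 ± 0.74 SE). Cxcl1 stood at 5.29 ± 3.33 and 206 ± 309 FPKM (3.66 ± 1.11), and Vcam1, an adhesion molecule, at 1.73 ± 0.510 and 4.95 ± 3.01 FPKM (1.02 ± 0.33). Interferon response genes were higher for 15 of 20 members (median 0.70, adjusted p = 0.00164, and adjusted p = 0.527 with an estimated correlation), with Ifit2 passing when adjusted over the list alone (3.58 ± 1.14 and 12.5 ± 4.64 FPKM). Stellate cell and matrix markers were higher for 11 of 13 members (median 0.67, adjusted p = 0.00164, and adjusted p = 0.465 with an estimated correlation), with Col1a1 and Col3a1 passing when adjusted over the list alone. Lymphocyte markers were higher for 7 of 8 members (median 0.75, adjusted p = 0.00209, and adjusted p = 0.492 with an estimated correlation), 3 of them passing when adjusted over the list alone. Ptprc, the common leukocyte antigen CD45, stood at 1.79 ± 0.468 and 5.00 ± 2.60 FPKM. Without pomegranate-high replicate 2 the mean change was 0.55 in place of 1.05 for inflammatory signalling, 0.36 in place of 0.62 for interferon response and 0.42 in place of 0.64 for the stellate list. The log2 difference was then 2.17 for Cxcl1, 0.64 for Vcam1 and 0.88 in place of 1.42 for Col1a1. In the fit excluding the 3 libraries with the highest mitochondrial share these 4 calls ended, with adjusted p = 0.449 for inflammatory signalling (mean change 0.39), 0.254 for interferon response (0.37), 0.987 for stellate cell and matrix markers (0.16) and 0.417 for lymphocyte markers (0.39 in place of 0.67). The call of the stellate cell and matrix markers also ended with the mitochondrial share as a covariate (0.191, mean change 0.44), and that of interferon response with a mean FPKM of at least 5 (0.0541, 0.44). Liver endothelial markers were lower for 8 of 11 members (median −0.46, adjusted p = 0.00164, and adjusted p = 0.465 with an estimated correlation), 0 of them passing when adjusted over the list alone. Stab1, an endothelial scavenger receptor, stood at 8.78 ± 2.33 and 3.52 ± 1.80 FPKM, and without pomegranate-high replicate 3 the adjusted p of the liver endothelial markers was 0.0812, with a mean change of −0.33 in place of −0.37.

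Triglyceride storage and lipid droplets (14 of 18 lower, median log2 difference −0.19, camera adjusted p = 0.0248) and glucose metabolism and insulin signalling (11 of 17 lower, median −0.33, 0.0248) fell as lists against the controls. Mitochondrially encoded transcripts rose as a list (11 of 12 higher, median 0.70, 0.0385). With an estimated correlation the adjusted p = 0.540, 0.465 and 0.676. When adjusted over the list alone 1 triglyceride gene passed, Lpin1, a phosphatidate phosphatase (17.6 ± 0.198 FPKM in controls, 5.02 ± 4.59 in the pomegranate-high arm, −1.88 ± 0.44 SE), and 0 of the other lists. The triglyceride storage and lipid droplets call was lost without control replicate 2 (0.0642, mean change −0.22 in place of −0.28) or pomegranate-high replicate 2 (0.138, −0.13), and its change was −0.51 without pomegranate-high replicate 3. The glucose metabolism and insulin signalling call was lost without control replicate 3 (0.0848, mean change −0.14 in place of −0.27) or pomegranate-high replicate 2 (0.116, −0.12), and its change was −0.43 without pomegranate-high replicate 3. The mitochondrially encoded transcripts lost their call without control replicate 2 (0.0672, mean change 0.57 in place of 0.66), control replicate 3 (0.287, 0.45), pomegranate-high replicate 1 (0.227, 0.56) or pomegranate-high replicate 2 (0.307, 0.38), and their change was 1.04 without pomegranate-high replicate 3. With the mitochondrial share as a covariate the calls ended for triglyceride storage and lipid droplets (0.370, mean change 0.03), glucose metabolism and insulin signalling (0.0637, 0.01) and mitochondrially encoded transcripts (0.227, −0.04). The glucose call was also lost with a mean FPKM of at least 5 (0.0707, −0.22) and with quantile normalization (0.0554, −0.34), and the mitochondrial call with no filter on low values (0.104, 0.66). In the fit excluding the 3 libraries with the highest mitochondrial share the triglyceride call ended (0.447, mean change 0.17), as did the glucose call (0.153, 0.05). In it the mitochondrially encoded transcripts turned lower in the pomegranate-high arm (mean change −0.11). The 3 libraries were excluded for their share of these same transcripts, so the loss of the rise was set by that choice. Plin2, which coats lipid droplets, stood at 130 ± 19.2 and 226 ± 85.3 FPKM. Fgf21, a hormone secreted by the liver, stood at 21.2 ± 9.24 and 120 ± 56.3 FPKM, and Cyp7a1 at 15.8 ± 1.98 and 55.0 ± 24.2 FPKM (1.64 ± 0.58).

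By limma with Benjamini-Hochberg adjustment, 2 of 11078 genes differed between the pomegranate-high arm and the controls. Asns (ENSRNOG00000007546, chromosome 4, 33743364 to 33761163, minus strand), asparagine synthetase, rose from 0.711 ± 0.440 to 6.99 ± 0.951 FPKM (log2 difference 2.25 ± 0.23 SE, adjusted p = 0.0165, range over 21 alternatives 0.0123 to 0.317). The pomegranate-high libraries stood at 7.93, 6.03 and 7.01 FPKM for Asns, and the model arm at 1.84 ± 0.316 FPKM. Of the 9 fits that each left out 1 library, Asns passed only without control replicate 2 (adjusted p = 0.0199), model replicate 1 (0.0360) or pomegranate-high replicate 3 (0.0126). RT1-CE16, of a multi-copy family, was lower, with 0.91 FPKM in 1 pomegranate-high library and listed at 0 in the other 2 (−2.49 ± 0.30, adjusted p = 0.0482, range over 21 alternatives 0.0196 to 0.317). The cause of these 0 values was not tested. RT1-CE16 passed only without pomegranate-high replicate 1 (0.0310) or pomegranate-high replicate 3 (0.0196) when 1 library was left out. Asns belongs to the list unfolded protein and integrated stress response, of which 14 of 19 members were higher without the list passing (median 0.37, adjusted p = 0.0849). At an unadjusted p under 0.05, regrouping the 6 libraries of both groups otherwise than labelled gave 104 to 1320 genes. The labelled groups gave 1125, where chance alone would give 553.9 on average. Leaving out 1 library moved this count between 588 (without pomegranate-high replicate 2) and 2306 (without pomegranate-high replicate 3), with 647 without control replicate 2. They were 802 higher and 323 lower, and under median-of-ratios scaling 610 higher and 558 lower. The balance turned with quantile normalization (594 higher, 597 lower) and with voom on recovered reads (576 and 601). Voom called 1 gene and gave 1177 at that level. Without pomegranate-high replicate 3, 328 genes passed, 151 higher and 177 lower. Among the other genes with the smallest p, Anxa7 (3.1 ± 0.43 and 11 ± 3.2 FPKM, 1.53 ± 0.24, adjusted p = 0.139) and Inpp1 (2.62 ± 0.0497 and 7.15 ± 1.40 FPKM, 1.16 ± 0.20) were higher without passing. So were Mthfd2, a mitochondrial folate enzyme (0.426 ± 0.380 and 2.61 ± 0.208 FPKM, 1.37 ± 0.24), and Ptgis, prostacyclin synthase (0.238 ± 0.183 and 2.02 ± 0.530 FPKM, 1.28 ± 0.23). Zbtb16, a transcription factor gene (9.24 ± 2.86 and 0.690 ± 0.658 FPKM, −2.63 ± 0.38), was lower without passing (adjusted p = 0.0861). In 16.1% of the genes the groups did not overlap, where chance gives 10% on average. The spread of that share over other splits was not computed.

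Several lists did not pass in any comparison. Over the comparisons of model with control, pomegranate-high with model and pomegranate-high with control, the adjusted p was 0.225, 0.0555 and 0.481 for acute phase genes and 0.0735, 0.120 and 0.945 for drug-metabolising enzymes. It was 0.136, 0.702 and 0.0849 for NRF2 targets and antioxidant enzymes, and 0.0846, 0.511 and 0.0849 for unfolded protein and integrated stress response. It was 0.960, 0.704 and 0.871 for apolipoproteins and lipoprotein handling, 0.985, 0.604 and 0.623 for AMPK, SIRT1 and autophagy, and 0.0948, 0.702 and 0.0947 for oxidative phosphorylation. For cell cycle genes it was 0.985, 0.463 and 0.454, for pericentral hepatocyte markers 0.0937, 0.871 and 0.170, and for bile duct cell markers 0.344, 0.241 and 0.0700. Neutrophil markers had 1 measured member, S100a9, and were not tested as a list. Within the acute phase list Lcn2, a lipocalin, passed in the third comparison when adjusted over the list alone (1.48 ± 0.527 FPKM in controls, 125 ± 175 in the pomegranate-high arm). Within the drug-metabolising list Cyp3a9, of a multi-copy family, did so as well.

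The last question was whether genes that differed between model and control moved back between pomegranate-high and model. By limma, 0 genes were called in both steps with opposite signs, with voom on recovered reads also at 0. At an unadjusted p under 0.05 in both steps, 78 genes had opposite and 3 the same sign. The model libraries enter both steps, and 100 simulations of unchanged groups that share them gave a mean of 143 such opposite genes (111 to 173), while independent lists would share 16.1. Tor3a, Dbp, Arntl, Per3, Hbb and Hba-a3 had opposite signs in the steps. Across genes, which are not independent replicates, the log2 differences of both steps correlated at r = −0.263, where the simulations, with all libraries, gave −0.500 (−0.534 to −0.462). Leaving out 1 library moved r between −0.499 (without model replicate 2) and −0.127 (without control replicate 3), and with the mitochondrial share as a covariate it was −0.396. Their covariance was −0.0383 against a simulated −0.0673. The simulations of this paragraph drew genes independently, with the same spread of a gene in all 3 groups. In the data the median SD was 0.23 in the controls, 0.33 in the model arm and 0.34 in the pomegranate-high arm. The simulated ranges may therefore be too narrow and off centre, and no conclusion is drawn from values outside them. The 3 model libraries are too few to be split between the steps with at least 2 in each part, so these values were not computed with separate model libraries. The differences of the 2 arms from the same controls correlated across genes at r = 0.463 (simulated 0.501, range 0.469 to 0.541), with a covariance of 0.0733 against a simulated 0.0676. RT1-CE16 was the 1 gene called in both, and no simulated number of shared calls was computed for arms that share their controls.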

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

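All tests in this part were chosen after the result was seen, except those of the clock genes without single libraries and of other splits of the libraries. The fits with the mitochondrial covariate and with the length trend were chosen after the data were seen, and their bounds were written before their own results were seen. Among 9158 genes left out of the tests for low values, 2 had 0 reads in all 3 controls and at least 5 reads in each pomegranate-high library. No gene did so for the model arm, and other assignments of the 6 libraries, 20 in all, gave at most 1. Ccl7 (chromosome 10, 69423086 to 69424979, plus strand), a chemokine gene that attracts monocytes, reached a mean of 2.21 FPKM ± 3.01 (SD, n = 3) from 8, 68 and 5 reads, with 2, 2 and 1 reads in the model arm. Asb15 (chromosome 4, 51614676 to 51644492, plus strand) reached 0.713 FPKM ± 0.495 from 18, 74 and 44 reads, with 68, 0 and 31 reads in the model arm.

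Circadian clock genes differed between the arms labelled pomegranate-high and model, and a shift in the time of day or of feeding at sampling may account for it, since it would move genes of opposite phase in opposite directions. The early-phase genes Arntl, Clock, Nfil3 and Cry1 were higher (4 of 4) and the late-phase genes Dbp, Nr1d1, Nr1d2, Per1, Per2, Per3, Tef and Hlf lower (8 of 8; Npas2, Ciart and Bhlhe41, also named for the test, were left out for low values), a difference of means of 2.07 log2 units (exact permutation p = 0.00202 over 495 ways to divide the genes, which are not independent). Between model and control the same difference was −1.48 (exact permutation p = 0.00808), and between pomegranate-high and control 0.59 (0.0828). Leaving out model replicate 1 or pomegranate-high replicate 1 or 2 kept at least 0.925 of the late-phase mean change of −1.30, which argues against these libraries as the cause. The directions were seen before the permutation test was chosen, so its p restates them. Sampling times are not given in the sources used here. An effect of the treatment on the clock could give the same opposite directions, so it stays open and was not tested.

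Blood, endothelial and macrophage markers were lower in the model arm than in the controls. Less residual blood alone is argued against by the endothelial markers, which changed by −0.79 (SE 0.14) beside −0.95 (SE 0.22) for red cell markers. A lower share of all cells other than hepatocytes would lower stellate markers alike, but endothelial minus stellate was −0.78 (SE 0.17), with stellate markers at −0.01 (SE 0.11). Without model replicate 1, the library with the highest mitochondrial share, the endothelial change was −0.72 (SE 0.16), 0.909 of that with all libraries, which argues against it as the source for endothelial markers, but the macrophage change was −0.37 in place of −0.76, a ratio of 0.487, so for macrophage markers that library stays a possible source. The changes of these lists were seen before these comparisons were chosen, so the values restate them and are no separate test. The stellate list also holds matrix genes such as Col1a1, whose level per cell was not measured. A difference in the sinusoidal cells or in how livers were drained or dissected stays open, and no biological explanation was tested.

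More genes differed from the controls in the pomegranate-high arm than in the model arm at an unadjusted p under 0.05 (1125 and 330, chance 553.9), counts that leaving out 1 library moved between 588 and 2306 and between 189 and 444. The mitochondrial share of the libraries might account for it: with the share as a covariate 988 genes remained at that level, over the bound of 830.85 written before this result was seen, but leaving out 1 library moved this count between 454 and 2784, and a fit excluding the 3 libraries with the highest share, which leaves 1 pomegranate-high library, gave 626 genes for pomegranate-high and 554 for model, so it stays open. A loss of reads that depends on gene length could do the same, and with the length trend removed there were 1164 genes (642 to 2222 leaving out 1 library), which leaves it open too. If the labels of both arms were exchanged, the arm with 1125 genes would be the model, and no value here decides that. An effect of the treatment that the design names also stays open. So does chance, since other splits of the same libraries gave 104 to 1320 genes for pomegranate-high with control. For model with control other splits gave 100 to 771 genes.

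Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. For model with control 1 of the 10 splits, the real one included, called as many genes as the real one (real 1, highest other 0) and 3 called as many lists (real 11, highest other 13). For pomegranate-high with model it was 1 for genes (real 1, highest other 0) and 2 for lists (real 16, highest other 19). For pomegranate-high with control it was 2 for genes (real 2, highest other 2) and 5 for lists (real 13, highest other 14). At an unadjusted p under 0.05, the split that set model replicate 1 and pomegranate-high replicates 1 and 2 against the rest of these arms gave 2216 genes and the real split 963. That split called 0 genes and 7 lists, against 1 and 16 for the real one, so the measures disagree. Its cause was not tested. Those are the 3 libraries with the highest mitochondrial share, but they were not alike. Model replicate 1 correlated at 0.891 and 0.917 with pomegranate-high replicates 1 and 2, which correlated at 0.946 with each other. For model with control the highest other split gave 771 genes and the real one 330, and for pomegranate-high with control 1320 and 1125.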

How the results depend on the processing

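Voom, the mitochondrial covariate, the fit excluding the 3 libraries with the highest mitochondrial share and the nuclear protein-coding genes were chosen after the data were seen. Genes past the threshold, given for model with control, pomegranate-high with model and pomegranate-high with control, numbered 1, 1 and 2. They were 0, 1 and 0 with a pseudocount of 0.1 or a mean FPKM of at least 5, 0, 0 and 0 with no filter or with the covariate, 1, 1 and 0 for TPM. They were 1, 0 and 1 for median-of-ratios scaling, 0, 0 and 1 for quantile normalization or voom, 1, 0 and 0 for the 2 groups alone. They were 10, 1 and 6 with library quality weights, 1, 1 and 1 without the trend, 2, 0 and 0 excluding the 3 libraries, and 1, 1 and 4 for nuclear protein-coding genes. An unadjusted p with at least 2-fold gave 83, 317 and 390. Leaving out 1 library gave 0 to 1, 0 to 77 and 0 to 328 genes, the 77 and 328 without pomegranate-high replicate 3 and all with the sign they had with every library. Counts of lists, 11, 16 and 13, became 0, 1 and 0 with an estimated correlation, stayed within 1.5 times elsewhere except for 8 in the third comparison excluding the 3 libraries, and ranged from 10 to 15, 12 to 20 and 11 to 16 leaving out 1 library. Of the called lists 5, 4 and 4 kept their call in every alternative with the preset correlation. Opposite changes in both steps numbered 0, and 1 with library quality weights, and 0 to 0 leaving out 1 library. The exact permutation p of the separation, 0.143, ranged from 0.129 to 0.214 over the other alternatives and from 0.025 (without pomegranate-high replicate 3) to 0.375 leaving out 1 library, and the correlation of both steps from −0.499 (without model replicate 2) to −0.127 (without control replicate 3). Of 648 values of the genes with the smallest p, 515 kept their sign and their side of the threshold or stayed within their error, and 0 reversed. Among all named genes 12 of 3094, 43 of 3020 and 24 of 2977 values reversed, 34 and 21 of the 43 and 24 excluding the 3 libraries, and 0 of these were called. Leaving out 1 library moved the log2 difference by over 1.5 times for 94 of 142, 95 of 139 and 79 of 137 named genes, and the mean change for 9 of 11, 8 of 16 and 8 of 13 called lists. Of the called lists, 1 was called the other way in an alternative. It was the mitochondrially encoded transcripts of pomegranate-high with control, excluding the 3 libraries. Those libraries were chosen by their share of these transcripts, so this turn is no separate evidence. Excluding the 3 libraries leaves 1 pomegranate-high library, assumed to vary like the other groups, and its separation test was not run. The cause of the other differences was not tested. Depths of 13678658 to 17966670 reads limit genes near the floor. No paired analysis was possible because the replicate numbers only follow the order of the samples.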

Other observations

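The tests of gene ontology terms in this part were all chosen after the data were seen. Of 798 terms, 1 passed for model with control, 24 for pomegranate-high with model (20 higher, 4 lower) and 18 for pomegranate-high with control (13 higher, 5 lower), by camera with a preset correlation, and 0 passed with an estimated correlation (smallest adjusted p = 0.993). Of the genes annotated to the chemokine-mediated signaling pathway, 10 of 11 were higher in the pomegranate-high arm than in controls (median log2 difference 1.05, adjusted p = 0.00243, highest leaving out 1 library 0.0126, and adjusted p = 0.999 with an estimated correlation), among them Ccl6, Ccl17, Ccl22, Cxcl11 and Cxcl2. The pomegranate-high libraries lay at 1.18, 2.13 and 0.47 for this pathway relative to the control mean, and without pomegranate-high replicate 2 the mean change was 0.83 in place of 1.26. Of the genes of tetrahydrofolate interconversion, which carry one-carbon units, 8 of 10 were lower (median −0.57, adjusted p = 0.00576, highest leaving out 1 library 0.0407, and adjusted p = 0.999 with an estimated correlation). They include Shmt1, Mthfd1 and Dmgdh. All 10 genes of intracellular sequestering of iron ion, among them the ferritin light chain genes Ftl1 and Ftl1l1, which can share reads, were higher in the pomegranate-high arm than in controls (median 0.72, adjusted p = 0.00447) and than in the model arm (0.70, 0.00975), with adjusted p = 0.999 and 0.993 with an estimated correlation. Both iron calls were lost without pomegranate-high replicate 3 (0.0958 and 0.139), though the mean changes hardly moved (0.70 in place of 0.74 and 0.67 in place of 0.70), and without model replicate 1 the mean change from the model arm was 0.44 in place of 0.70. Pomegranate-high replicate 1 (1.02) and model replicate 1 (−0.49) were the extremes for this term. They also had the largest shifts of long minus short genes (−0.64 and 0.43 log2 units), whose part in this term was not tested.

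Of the genes with known roles beside Asns in amino acid stress, named after their values were seen, the regulator Atf4 stood at 66.7 ± 9.93 FPKM in controls, 61.2 ± 12.7 in the model arm and 112 ± 47.9 in the pomegranate-high arm (SD, n = 3). Sesn2, like Asns a known target of Atf4, stood at 24.9 ± 3.55, 23.2 ± 4.67 and 12.1 ± 5.44 FPKM. Neither passed over all genes in any comparison. They are only part of the list unfolded protein and integrated stress response and do not stand for it. Of its 19 members 14 were higher in the pomegranate-high arm than in controls, without the list passing (camera adjusted p = 0.0849).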
